A study of Rattus norvegicus with 4 samples.

How the data were processed

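Small RNA was sequenced from exosomes, the small membrane vesicles that cells release, of rat (Sprague-Dawley) origin. Per the labels' protocols, exosomes of adipose tissue (Exo-AT) came from minced explants of animals aged 4 weeks, kept in a spinner flask with 75 mL of medium at 100 rpm for 3 days, and exosomes of adipose stem cells (Exo-ADSCs) came from passage 3 cells kept in serum-free medium for 3 days. Total RNA was ligated to adaptors, amplified, size-selected for inserts of about 15 to 35 nt and read for 36 cycles on an Illumina HiSeq. The series holds 4 libraries in 2 groups, 2 per group, with groups and replicate numbers taken from the sample titles. Nothing says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

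Each tag file gives, per the file headers, whole-number counts for every distinct read sequence (tag) and the precursor hairpin it was aligned to. The hairpins are either named rat miRNA precursors or hairpins that the authors predicted themselves. In the files, tags had at least 2 reads, and reads of a tag aligned to several hairpins were divided between them. The submitters' processing notes name Novoalign 2.07.11 and the rn6 assembly. The adaptor trimming, the release of the miRNA reference and the method of hairpin prediction are not given in the sources used here. Tag counts were used for 3 of the 4 libraries. The file of Exo-ADSCs replicate 1 holds a summary of alignments by class of read count, a unit of its own (other), and percents of the same numbers, per the file headers, so Exo-ADSCs entered every test as 1 library. A table of the whole series lists 45 miRNAs as raised in Exo-AT. In it the authors give a value headed normalized reads (a score here, since the factor is not stated) for all 4 libraries, the authors' mean score per group, and a fold. The fold, a ratio, was deposited by the authors and equals the Exo-AT mean plus 10 over the Exo-ADSCs mean plus 10 in 45 of the 45 entries.

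Tags on named hairpins were summed to mature miRNAs. A tag was given the 5p arm where its midpoint lay in the first part of the hairpin up to the hairpin's midpoint and otherwise the 3p arm, with positions corrected for the 5 bases that the files count before the hairpin, and genomic copies of a miRNA were summed. This gave 348 miRNAs with a count in at least 1 library. Predicted hairpins were left out of the tests. Named-miRNA totals were 97204 counts in Exo-ADSCs replicate 2, 9134 in Exo-AT replicate 1 and 136024 in Exo-AT replicate 2. A count of 0 allows up to 3 counts, which is 30.9, 328 and 22.1 CPM (counts scaled to the library's total of named miRNAs) in these libraries. Shares of counts have Wilson 95% intervals. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

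The test was edgeR 4.0.16 (quasi-likelihood, two-sided, R 4.3.3) on counts with TMM scaling, whose factors were 0.664, 1.39 and 1.08 for the libraries in the order above. miRNAs were kept by edgeR's default expression filter (minimum count 10, minimum total 15), which left 183. p-values were adjusted by Benjamini-Hochberg over these 183 and called at 0.05. With 1 library in the Exo-ADSCs group, the fit takes its spread from the 2 Exo-AT libraries and assumes that the lone library varies like them, with 1 residual degree of freedom per miRNA. The tag files of both Exo-AT libraries carry the same sample name inside, so whether they come from separate samples is open, and every dispersion, SD and p-value rests on them. CPM values given as mean ± SD are TMM-scaled, SD over the 2 Exo-AT libraries. A fold against a group with 0 counts is given as a bound, with the group at 3 counts over all its libraries, and a ratio that rests on 1 to 3 counts has an exact (Clopper-Pearson) counting interval.

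The test was tested on simulated negative binomial counts with the miRNA means, the library sizes and the common dispersion of these data (0.115), in 50 runs with 20 miRNAs changed per fold size. It recovered 27.4% of 4-fold and 53.4% of 8-fold changes, and 6.48% of the calls were false. As many miRNAs were raised as lowered in each run, so these rates do not cover errors of scaling under unbalanced changes. With no change the median was 0 calls and the highest 2. When the lone library had 4 times the dispersion of the others, the median was 4 calls and the highest 33.

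A set of 18 miRNA lists was fixed before the data were examined, as were the tests and the rule for naming miRNAs. A list member took in both arms of its hairpin, so the tested forms of a list include opposite-arm products. Lists with at least 5 tested members, 13 in all, were tested with camera (limma 3.58.1, correlation preset at 0.01). The rule named the 10 highest and 10 lowest log2 fold changes among called miRNAs whose groups did not overlap, the 10 most abundant miRNAs of each group, up to 4 of the most abundant members of each list, and the 5 largest folds in the authors' deposited table. The rule gave 71 miRNAs, of which the text names a part. Correlations used log2(CPM + 1). Alternatives were DESeq2 1.42.0, limma on log2(CPM + 1), other scalings, other filters, a fold threshold, counting of only the most common tag, and leaving out each Exo-AT library. Alternatives added after the data were seen were the inclusion of predicted hairpins, tags of 20 to 25 nt only, tags without a mismatch, tags of a lone hairpin only, let-7a without its extended tags, and other scalings for the comparison with the authors' table. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No genome was used, and the RefSeq gene table of assembly GRCr8 served only to see which miRNA genes neighbour each other.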

Results

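The libraries profiled miRNAs in exosomes of rat adipose tissue explants (Exo-AT) and of cultured rat adipose stem cells (Exo-ADSCs), 2 libraries each. Counts per read sequence were used for Exo-ADSCs replicate 2, with 715114 counts assigned to hairpins, Exo-AT replicate 1 with 15200 and Exo-AT replicate 2 with 181049. Exo-ADSCs replicate 1 entered only through the authors' deposited table. Exo-ADSCs values from tag counts therefore rest on 1 library and have no SD.

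The main comparison asked which miRNAs differ between the vesicles of the tissue and those of its stem cells. Exo-AT carried more miR-99a-5p, miR-126a-3p, miR-30d-5p, miR-26a-5p and miR-450a-5p, and Exo-ADSCs carried more miR-99b-5p, let-7a-5p, miR-22-3p, miR-24-3p and miR-210-3p. The miR-99/100 family, which shares a seed sequence, split: miR-99a-5p was at 40939 ± 1237 CPM in Exo-AT (SD, n = 2) against 1855 CPM in Exo-ADSCs, whereas miR-99b-5p was at 23005 ± 106 CPM against 338831 CPM, a call that was lost with tags of 20 to 25 nt only (log2 fold change of miR-99b-5p -0.44). miR-10b-5p, the most abundant miRNA of both Exo-AT libraries, was at 215340 ± 52017 CPM in Exo-AT and 199010 CPM in Exo-ADSCs, and did not pass the test (log2 fold change 0.11, SE 0.24). Of 183 miRNAs tested, 35 were higher and 35 lower in Exo-AT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the authors' predicted hairpins included, an alternative added after the data were seen, the same test called 0 of 401, with 25 at an unadjusted p under 0.05. The predicted hairpins of the 2 Exo-AT libraries shared 33 exact sequences, of 89 and 313. Hairpins that differ only at their ends were kept apart, such as a chromosome 2 pair with the same leading tag (142 and 1185 counts). Most predicted hairpins as entered thus had counts in only 1 of the libraries that give the fit its spread. The loss of calls therefore cannot be told apart from this matching or from a difference in hairpin sets.

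Among the miRNAs higher in Exo-AT, several had 0 counts in Exo-ADSCs. miR-450a-5p had 58 and 513 counts in the Exo-AT libraries and was at least 76.5-fold higher (adjusted p = 1.57e-19, edgeR). let-7d-3p was at least 11.9-fold, miR-203b-3p at least 10.2-fold and miR-150-5p, a lymphocyte miRNA, at least 9.51-fold higher. The bound for miR-150-5p rests mostly on Exo-AT replicate 2, with 69 counts against 2 in Exo-AT replicate 1 (314 ± 220 CPM). The bounds for miR-382-5p, miR-205-5p and miR-411-5p were 8.31-fold, 6.83-fold and 6.56-fold. miR-379-5p was at 1718 ± 81.6 CPM against 3 counts in Exo-ADSCs, a ratio of 37.8 with a counting interval of 12.8 to 184. miR-9a-5p, best known from neurons, also had 3 counts there, and its ratio was 16.5 (interval 5.51 to 81), with a wide spread in Exo-AT (1827 ± 1776 CPM). The log2 fold change of miR-9a-5p was 3.48 without Exo-AT replicate 1 and 5.73 without Exo-AT replicate 2. miR-450b-5p rose by 4.91 on the log2 scale (SE 0.68), but 96.2% of its counts in Exo-AT replicate 2 came from tags that also align to miR-450a.

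For the abundant miRNAs higher in Exo-AT the values are log2 fold changes, which cannot be ranked against the bounds above, given as plain folds. The log2 fold change was 4.46 (SE 0.36) for miR-99a-5p, 2.82 (SE 0.52) for miR-125b-5p, 2.16 (SE 0.35) for miR-101a-3p and 2.19 (SE 0.36) for miR-25-3p. miR-486-5p, an erythroid and muscle miRNA, was called at 0.93 (SE 0.27), yet the Exo-AT libraries lay on both sides of Exo-ADSCs (94933 ± 82388 CPM against 49869 CPM). The log2 fold change of miR-486-5p was -0.40 without Exo-AT replicate 2 and 1.62 without Exo-AT replicate 1.

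Among the miRNAs lower in Exo-AT, let-7a-5p fell by 5.67 on the log2 scale (SE 0.28, adjusted p = 8.63e-47 by edgeR). In Exo-ADSCs 72.2% of its counts began 3 nt before the usual start, and without those tags its log2 fold change was -3.83. miR-24-3p stood at -5.13 (SE 0.36), miR-210-3p, the classic hypoxia-induced miRNA, at -4.72 (SE 0.44) and miR-22-3p at -3.68 (SE 0.32). miR-99b-5p and miR-100-5p were at -3.88 and -3.13 (SE 0.25 each). With tags of 20 to 25 nt only, an alternative added after the data were seen, the log2 fold change of miR-100-5p was 0.35, and neither was called. miR-297-3p (302 counts in Exo-ADSCs and 0 in Exo-AT) was at least 250-fold lower in Exo-AT, and 23.2% of its counts came from tags that also align to predicted hairpins. miR-21-3p was at least 69.7-fold, miR-6328-5p at least 47.3-fold and miR-466b-5p, which has many genomic copies, at least 39.8-fold lower. Smaller bounds were found for miR-146b-3p (26.5-fold), for miR-215-5p, miR-194-5p and miR-3557-5p (19.1-fold each) and for miR-300-5p (14.9-fold). The very abundant miR-143-3p and miR-21-5p were at -0.87 (SE 0.24) and -0.97 (SE 0.27). With total-count scaling the log2 fold change of miR-143-3p was 0.04 and the log2 fold change of miR-21-5p was -0.07, and neither was called.

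**Figure D1:**
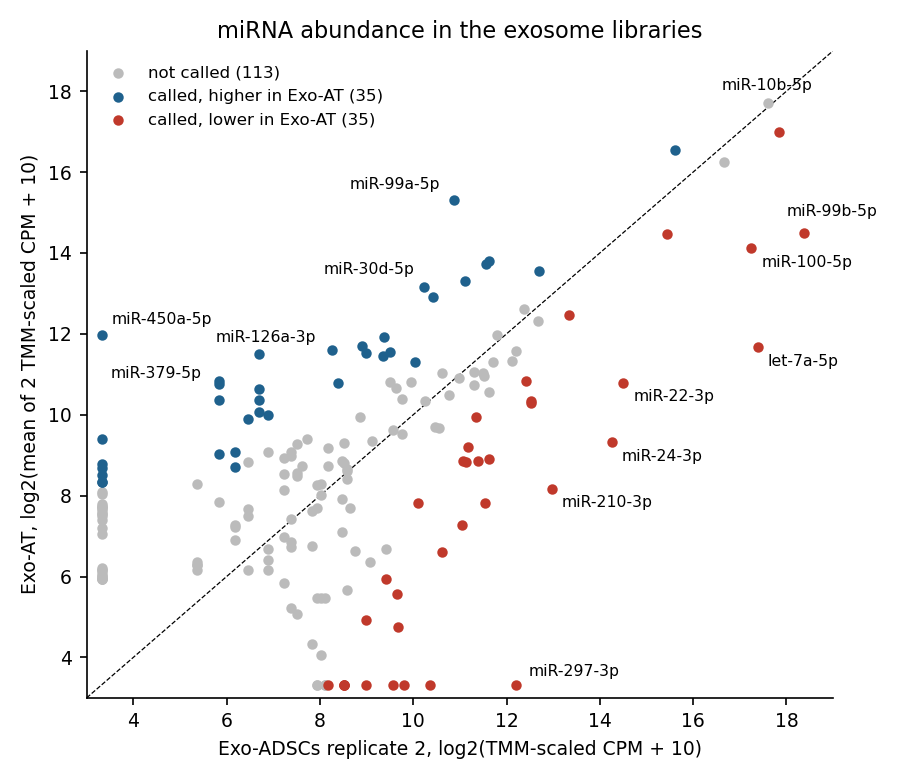
Abundance of the 183 tested miRNAs, on log2 axes after adding 10 to TMM-scaled CPM, with Exo-ADSCs replicate 2 on the x axis and the mean of the 2 Exo-AT libraries on the y axis. Each point is a miRNA, the dashed line marks equal abundance, and colours show the 35 called higher and the 35 called lower in Exo-AT.

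The split between directions depended on scaling and on which tags were counted. The median log2 fold change of all 183 miRNAs was 0.37 with TMM, 0.08 with DESeq2 size factors and 1.21 with total-count scaling. The calls were 23 higher and 30 lower with DESeq2 size factors and 46 and 19 with total counts. Counting only the most common tag of each miRNA, with TMM, gave 37 and 18 of 144 tested. That tag was picked by its summed share over 3 libraries, 2 of them Exo-AT, which can favour forms common in Exo-AT. Relative to the TMM median, miR-99a-5p was at 4.09, miR-450b-5p at 4.54, let-7a-5p at -6.05 and miR-24-3p at -5.50. The calls held under all 4 scalings for 39 miRNAs, 21 higher and 18 lower, and with DESeq2 and limma as well for 16, 9 higher and 7 lower. DESeq2 called 43 and limma 25.

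The lists fixed beforehand described which kinds of miRNA moved. In the imprinted Dlk1-Dio3 cluster, a large group of miRNA genes expressed from the maternal chromosome, 5 of 15 tested forms were higher in Exo-AT (miR-127-3p, miR-379-5p, miR-382-5p, miR-411-5p and miR-434-3p), miR-300-5p was lower, and 9 were not called. The counts adjusted over the list alone were also 5 and 1. miR-434-3p was at 1591 ± 462 CPM against 93.5 CPM (log2 fold change 4.11, SE 0.79) and miR-127-3p at 1747 ± 11.3 CPM against 327 CPM. The median log2 fold change was 5.16, or 2.05 with miRNAs at 0 counts set to their bound. It was the only list of 13 called by camera (adjusted p = 0.0211 by limma's camera test with Benjamini-Hochberg adjustment), with adjusted p = 0.722 with an estimated correlation, adjusted p = 0.14 by fry and adjusted p = 0.136 with total-count scaling.

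In the miR-30 family, 4 of 7 forms were higher in Exo-AT and none lower, with 4 and 0 adjusted over the list alone. miR-30d-5p was at 9173 ± 2130 CPM against 1184 CPM (2.96, SE 0.39), and miR-30a-5p, miR-30e-5p and miR-30e-3p stood at 2.17, 2.56 and 3.48. Of the forms not called, miR-30a-3p was at 1.69, miR-30c-5p at -0.20 and miR-30b-5p at -2.13. Of the let-7 family, let-7a-5p, let-7a-3p and let-7f-5p were lower, let-7d-3p was higher and 6 of 10 were not called, let-7i-5p (-0.33) and let-7c-5p (-0.61) among them. let-7a-3p and let-7d-3p are opposite-arm forms, and let-7d-5p was not tested (4 counts in Exo-ADSCs replicate 2, 0 and 5 in Exo-AT). let-7f-5p was at -0.86 (SE 0.32), and with total-count scaling the log2 fold change of let-7f-5p was 0.01. The adipocyte and pro-adipogenic list had 4 of 17 higher (miR-26a-5p, miR-30a-5p, miR-30d-5p and miR-204-5p) and 4 lower, including miR-378a-3p (-1.59, SE 0.38), miR-103-3p and miR-107-3p, which share reads with each other. The anti-adipogenic list had 2 of 19 higher, miR-27b-3p at 2.02 and let-7d-3p, and 5 lower, among them miR-130a-3p at -3.53 (SE 0.68) and miR-31a-5p. In each library 100% of the miR-130a-3p and miR-103-3p counts came from tags that also align to predicted hairpins, and miR-130a-3p was at 79.0 and 211 CPM in the Exo-AT libraries against 2088 CPM. Adjusted over the list alone, the adipocyte list had 4 and 4, the anti-adipogenic list 2 and 6, and the let-7 list 1 and 3. The camera values of these 4 lists were adjusted p = 0.206 for miR-30, 0.206 for let-7, 0.761 for the adipocyte and 0.362 for the anti-adipogenic list (limma).

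Of the mesenchymal stromal list, 9 of 28 forms were lower in Exo-AT, including miR-100-5p, miR-22-3p, miR-214-3p (-4.06, SE 0.83) and miR-21-3p, and 4 were higher, miR-99a-5p, miR-125b-5p, miR-351-5p and miR-450a-5p. miR-351-5p had 0 counts in Exo-AT replicate 1 and 120 in Exo-AT replicate 2, against 4 in Exo-ADSCs. Of the members called lower, miR-99b-5p and miR-100-5p had short reads in Exo-ADSCs (mean 17.6 and 17.8 nt) and were not called with tags of 20 to 25 nt only (the log2 fold change of miR-100-5p was then 0.35). Of the fibrosis-related list, 4 of 8 were lower, miR-21-5p, miR-21-3p, miR-192-5p and miR-214-3p, whereas miR-29a-3p stood at -0.23 (SE 0.51). Of the stress and hypoxia list, 4 of 6 were lower, miR-210-3p, miR-21-3p, miR-21-5p and miR-146a-5p. Without Exo-AT replicate 1 the log2 fold change of miR-146a-5p was -0.60, and it was -3.35 without Exo-AT replicate 2. Of the angiogenesis-promoting list, miR-126a-3p and miR-27b-3p were higher and 4 of 11 lower, miR-210-3p, miR-130a-3p, miR-31a-5p and miR-378a-3p. The counts adjusted over the list alone were the same 9 and 4, 4 and 0, 4 and 0, and 4 and 2. By camera none was called (adjusted p = 0.164 for the first 3 lists and 0.626 for the last, limma).

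Markers of other cell types were mixed. The endothelial miR-126a-3p was at 3077 ± 998 CPM in Exo-AT against 296 CPM, a log2 fold change of 3.40 (SE 0.56), and miR-126a-5p stood at 1.83 (SE 0.91) and passed when adjusted over the list alone and with total-count scaling. Of the erythroid and platelet list, 4 of 8 were higher, miR-16-5p (2.60), miR-15a-5p (3.26), miR-25-3p and miR-486-5p, and miR-423-5p was lower (-1.97). miR-451-5p of the same list stood at -0.01 and was not called. Of the leukocyte list, miR-150-5p was higher, miR-146a-5p and miR-146b-3p were lower, and 5 of 8 were not called. The muscle miRNA miR-1b-3p had 3 counts in Exo-ADSCs and 195 in Exo-AT, a ratio of 26.1 (interval 8.81 to 128), and the other 3 muscle forms were not called. The epithelial list had 6 of 12 lower, among them miR-203a-3p (-3.87, SE 0.61), miR-192-5p (-2.68, SE 0.57) and miR-183-5p (-2.45, SE 0.52), and 2 higher, miR-203b-3p and miR-205-5p. miR-183-5p was at 158 and 782 CPM in the Exo-AT libraries against 3132 CPM. Without Exo-AT replicate 1 the log2 fold change of miR-182-3p was -1.53 and without Exo-AT replicate 2 it was -3.62. In the neural list miR-9a-5p was higher and 3 of 4 were not called. The liver miRNA miR-122-5p stood at 0.37 (SE 0.94). Of the miR-17-92 clusters, miR-25-3p and miR-19b-3p (2.98, SE 1.24) were higher, 6 of 8 were not called, and miR-92a-3p was at 0.18. No form of the H19 and Igf2 list was tested. Adjusted over the list alone, the numbers higher and lower were 2 and 0 for endothelial, 4 and 1 for erythroid, 1 and 3 for leukocyte, 1 and 0 for muscle, 2 and 6 for epithelial, 1 and 0 for neural, 0 and 0 for liver and 1 and 0 for miR-17-92. The camera test sets a list against the other tested miRNAs, and the median log2 fold change of all 183 was 0.37. It put the leukocyte and angiogenesis-promoting lists lower, with medians of 0.10 and 0.18. The anti-adipogenic list had a median of -0.33 and a mean of 0.57. With total-count scaling the numbers higher and lower were 5 and 0 for the adipocyte list, 2 and 2 for anti-adipogenic, 5 and 6 for mesenchymal, 1 and 1 for let-7, 2 and 3 for epithelial, 4 and 2 for angiogenesis-promoting and 0 and 2 for stress and hypoxia. They were 1 and 3 for fibrosis, 2 and 1 for leukocyte, 5 and 0 for erythroid, 2 and 0 for endothelial, 2 and 0 for neural, 4 and 0 for miR-17-92 and 6 and 0 for Dlk1-Dio3, and for muscle, liver and miR-30 the same as with TMM. The tested lists among the cell type markers had camera adjusted p = 0.711 (erythroid), 0.761 (leukocyte), 0.419 (epithelial) and 0.626 (miR-17-92, limma).

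**Figure D2:**
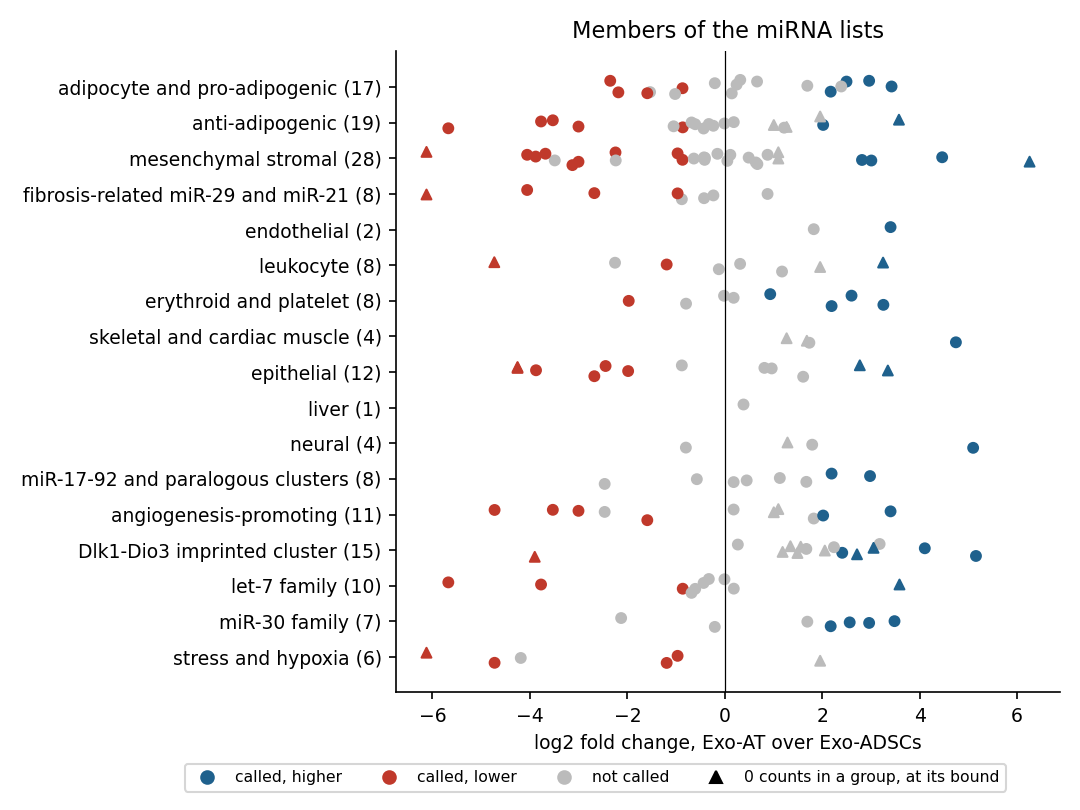
The log2 fold change of Exo-AT over Exo-ADSCs for each tested member of the lists, with the number of tested forms beside each list and vertical scatter only for legibility. Blue points were called higher, red points lower and grey points not called, and triangles are miRNAs with 0 counts in a group, drawn at their bound; all 4 called miR-30 forms lie right of 0.

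Each library was dominated by few miRNAs. miR-99b-5p led Exo-ADSCs replicate 2 with 22.4% of named counts, and miR-10b-5p led Exo-AT replicates 1 and 2 with 24.7% and 27.2%. The 10 most abundant miRNAs held 88.4%, 77.5% and 79.9% of named counts, in the same order. Counts were found for 264, 140 and 244 miRNAs, and after thinning all libraries to 9134 counts for 162, 140 and 168. Hairpins predicted by the authors took 86.4% of assigned counts in Exo-ADSCs replicate 2 (Wilson 95% interval 86.3 to 86.5), 39.9% in Exo-AT replicate 1 (39.1 to 40.7) and 24.9% in Exo-AT replicate 2 (24.7 to 25.1). Values per library have no test, as tag counts of 1 Exo-ADSCs library were used.

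Taken over all named miRNAs, reads in Exo-ADSCs were shorter. On named hairpins the most common length was 22 nt in both Exo-AT libraries and 18 nt in Exo-ADSCs replicate 2. Lengths of 21 to 23 nt, the size of intact miRNAs, held 71.5% and 75.8% of named counts in Exo-AT and 24.8% in Exo-ADSCs. The shortening differed between miRNAs: in Exo-ADSCs the mean length of miR-99b-5p was 17.6 nt, of miR-100-5p 17.8 nt and of miR-10b-5p 18.8 nt, against 19.3, 20.7 and 21.1 nt in Exo-AT replicate 2, while miR-21-5p was at 21.8 nt against 21.6 nt and miR-101a-3p at 21.2 nt in both. Some miRNAs had longer reads in Exo-ADSCs than in Exo-AT replicate 2: let-7a-5p (24.2 against 21.3 nt), miR-486-5p (24.4 against 22.3 nt) and miR-425-5p (25.2 against 22.2 nt). Arm use was alike in 36 of the 37 hairpins with at least 20 counts in every library, in that the same arm held the majority. The exception was miR-320, with 10.8% of counts from the 5p arm in Exo-ADSCs replicate 2 and 67.6% and 49.8% in Exo-AT. Its 5p tags were short in Exo-AT (mean 16.4 and 16.7 nt), and 100% and 97.9% of their counts there carried a mismatch or indel, against 84.8% in Exo-ADSCs replicate 2.

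**Figure D3:**
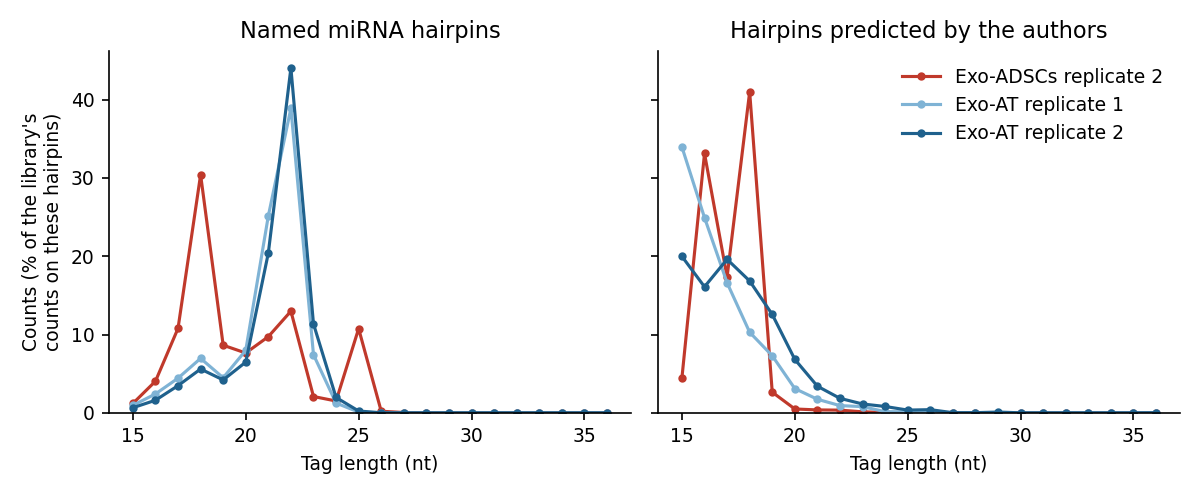
Length of tags in nt on the x axis and percent of each library's counts on the hairpins of that panel on the y axis, for named miRNA hairpins (left) and hairpins predicted by the authors (right). Each line is a library; on named hairpins the Exo-AT libraries peak at 22 nt and Exo-ADSCs replicate 2 at 18 nt, and predicted hairpins hold 0.842% to 6.38% of their counts at 21 to 23 nt.

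In tag counts, the Exo-AT libraries were closer to each other than to Exo-ADSCs replicate 2. Across 348 miRNAs, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.81 between the Exo-AT libraries, 0.48 between Exo-ADSCs and Exo-AT replicate 1 and 0.33 between Exo-ADSCs and Exo-AT replicate 2. Spearman's rho was 0.829, 0.487 and 0.387. Among the 49 miRNAs with at least 10 counts in every library, r was 0.97, 0.61 and 0.60. The authors' deposited table, which holds all 4 libraries but only 45 miRNAs chosen as raised in Exo-AT, did not show this order: on its log2 values r was 0.797 between the Exo-AT columns, 0.868 between the Exo-ADSCs columns, and 0.871, 0.826, 0.677 and 0.795 between an Exo-AT and an Exo-ADSCs column. Its first Exo-AT column followed the counts of all tags in 36 of 45 miRNAs. The second followed the most abundant tag alone in 29 of 45. The r between them thus mixes 2 ways of counting and does not measure how well the Exo-AT libraries agree.

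The authors' deposited table gives their own comparison over all 4 libraries, for 45 miRNAs listed as raised in Exo-AT. Its folds ran from 1.42 to 56.7. In the authors' deposited table the 5 largest were 56.7 for miR-450a-5p, 42.0 for miR-99a-5p, 28.0 for miR-125b-5p, 27.9 for miR-126a-3p and 24.8 for miR-434-3p. In 40 of its 45 miRNAs both Exo-AT values lay above both Exo-ADSCs values. Chance gives this for 16.7% of unselected miRNAs, but the 45 were chosen as raised on these same libraries, so the shares cannot be compared. The exceptions were miR-92a-3p, miR-199a-5p, miR-486, miR-28-3p and miR-21-5p. Of the 44 that could be tested on the tag counts, 38 had a log2 fold change above 0, 22 were called higher in Exo-AT, 20 were not called and 2, let-7f-5p and miR-21-5p, were called lower. These were chosen by the authors on the same libraries, so the count is not independent evidence of direction. With tag counts scaled to all assigned counts, 45 of the 45 were higher in Exo-AT with a median log2 fold of 4.23, with named-miRNA counts 44 and 2.60, and with TMM 39 and 1.71. Over all 183 tested miRNAs the same scalings gave 155, 130 and 102 higher, with medians of 2.79, 1.16 and 0.27. With Exo-AT replicate 1 alone the last 2 medians were 0.48 and -0.24, and with Exo-AT replicate 2 alone 1.28 and 0.59.

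**Figure D4:**
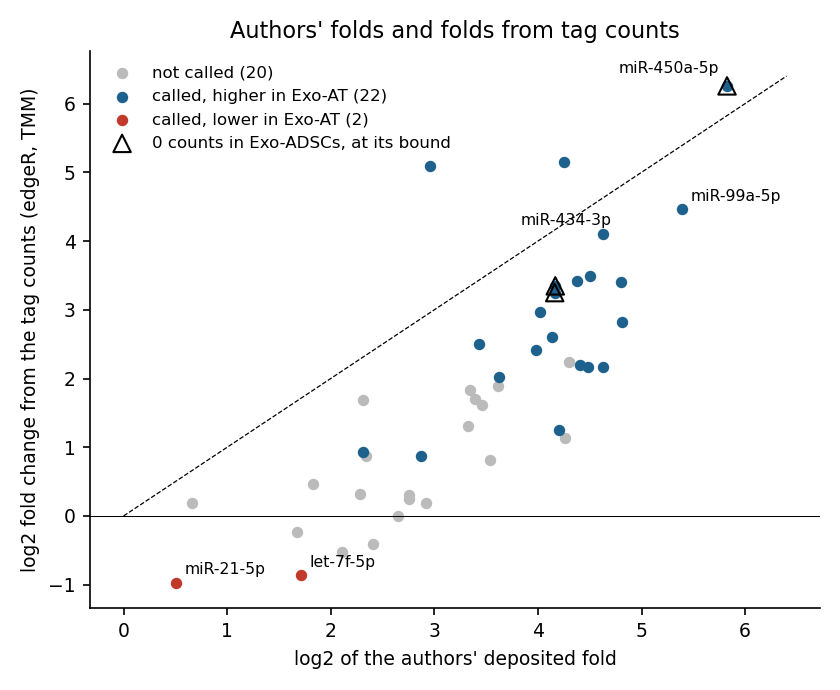
The log2 of the fold in the authors' deposited table on the x axis and the log2 fold change from tag counts on the y axis, for the 44 tested miRNAs of that table. Each point is a miRNA, the dashed line marks equal values, triangles mark miRNAs with 0 counts in Exo-ADSCs drawn at their bound, and the 2 called lower lie at the left.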

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

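All tests in this part were chosen after the results were seen. Reads on hairpins that the authors predicted lie outside the miRNA comparisons. They took 86.4% of assigned counts in Exo-ADSCs replicate 2, 39.9% in Exo-AT replicate 1 and 24.9% in Exo-AT replicate 2. The 2 leading hairpins of Exo-ADSCs replicate 2 held 529761 counts, 74.1% of its total, and their most common tags were AGGAAACTCTGGTGGAGG with 218684 counts and CGGCGACTCTGGACGC with 159030 counts.

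The pattern weighed here is the high share of predicted hairpins in Exo-ADSCs replicate 2. A different set of predicted hairpins does not account for the gap to Exo-AT replicate 2. On the 230 hairpins that Exo-ADSCs replicate 2 shared with it the shares were 86.4% and 24.4%, a wider gap than that between the Exo-AT libraries. These 230 include the 2 leading hairpins, with 2322 counts in Exo-AT replicate 2 and 0 in Exo-AT replicate 1. Hairpins were matched by exact sequence, which misses a hairpin predicted with shifted ends. By this match Exo-AT replicate 1 shared 24 of its 89 predicted sequences with Exo-ADSCs replicate 2, so for that library a different set stays open. The 2 leading hairpins carry much of the high share. Whether they are the whole of it is open, since the share without them was 47.6% against 39.9% and 23.9% in Exo-AT, a smaller gap than that between the Exo-AT libraries. Fragments of other RNAs, placed on a predicted hairpin with a mismatch, may also be part of the high share. The mismatch share of 96.4% alone does not decide this: it was 78.0% and 66.9% in Exo-AT, and without the 2 leading hairpins 74.9% in Exo-ADSCs replicate 2. On the 2 leading hairpins, 99.96% and 99.98% of counts in Exo-ADSCs replicate 2 carried a mismatch or indel. Nearly none of those reads matched the hairpin as predicted, and the RNA they came from was not identified. The source of the exosomes stays open as well and cannot be told apart from these, because tag counts of 1 Exo-ADSCs library were used and no ribosomal or transfer RNA reference was used to place the tags.

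The file of Exo-ADSCs replicate 1 gives a summary by class of read count, a signal outside the comparisons. Its line A counts 4742 alignments to named hairpins in 4 classes of 3613, 898, 192 and 39, and its line B counts 713. The classes of line B (593, 107, 12 and 1) equal those counted from the tags of Exo-AT replicate 1, and line A was tied to no tag counts.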

How the results depend on the processing

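The alternatives with predicted hairpins, tags of 20 to 25 nt, tags without a mismatch, let-7a without extended tags and single-hairpin tags were chosen after the data were seen; the others were planned. Of 183 miRNAs, 70 were called by edgeR with TMM. DESeq2 called 43 (22 higher and 21 lower), upper-quartile scaling 46 (21 higher) and limma 25 (9 higher and 16 lower). DESeq2 size factors gave 23 higher, total-count scaling 19 lower and the most common tag 18 lower. With predicted hairpins included, edgeR called 0 of 401, with 25 at an unadjusted p under 0.05. The cause was not tested for any of these. Matched by exact sequence, the predicted hairpins of the 2 Exo-AT libraries overlapped little, which limits the run that includes them. The most common tag was picked by its summed share over 3 libraries, 2 of them Exo-AT, which can favour forms common in Exo-AT. Total calls were within 1.5 times of 70 with the other scalings, filters, tag choices and a fold threshold. The miRNAs called changed more than these totals. With tags of 20 to 25 nt, 130 miRNAs were tested, and 42 of the 59 called were among the 70. With the most common tag 42 of 55 were, and with 10 counts in every library of a group 57 of 70. For lists, 1 was called, against 0 with an estimated correlation, 0 by fry and 0 with total-count scaling; the cause was not tested.

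Thinning to 9134 counts left 162 miRNAs detected and 45 with at least 10 counts in Exo-ADSCs replicate 2, and 168 and 59 in Exo-AT replicate 2, because fewer counts were kept. For miRNAs with at least 10 counts in all libraries r was 0.61 (Exo-ADSCs and Exo-AT replicate 1), 0.60 (Exo-ADSCs and Exo-AT replicate 2) and 0.97 (both Exo-AT). Over all 348 miRNAs r was 0.61, 0.58 and 0.88 with pseudocount 10, in the same order. It was 0.45, 0.27 and 0.79 with pseudocount 0.5, against 0.48, 0.33 and 0.81 with pseudocount 1. In hairpins with at least 100 counts the pooled 5p share was 78.8%, 71.6% and 81.1%, against 78.2%, 69.7% and 78.6%. The cause was not tested.

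Of the 70 named miRNAs tested, DESeq2 left 54 with the same call and 16 no longer called, DESeq2 size factors 56 and 14, upper-quartile scaling 52 and 18, limma 40 and 28, and the inclusion of predicted hairpins 19 and 46 of 65 compared. DESeq2 gave no adjusted p for 22 of the 183 miRNAs. Any named miRNA among these was counted with the same call unless its direction reversed. Reversals were few, and the cause was not tested. With total-count scaling the log2 fold change of miR-143-3p was 0.0421 and the log2 fold change of let-7f-5p 0.00925, and with limma the log2 fold change of miR-143-3p was 0.0143 and the log2 fold change of let-7f-5p 0.0145. With the most common tag the log2 fold change of miR-10a-5p was 2.71 and the log2 fold change of miR-182-3p 0.28. With tags of 20 to 25 nt the log2 fold change of miR-10a-5p was 1.34 and the log2 fold change of miR-100-5p 0.35. The log2 fold change of miR-486-5p ranged from -0.40 (without Exo-AT replicate 2) to 1.62 (without Exo-AT replicate 1).

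Leaving out an Exo-AT library gives 1 library against 1, values with no test. Among the 70 named miRNAs, those called in the main test reversed direction in 0 cases without replicate 1 and in 1 without replicate 2. For named miRNAs not called in the main test, changes of direction were not scored. Without Exo-ADSCs replicate 2 no comparison of tag counts was left. No paired analysis was possible because 3 libraries with a replicate block leave no residual degrees of freedom. Depth limits Exo-AT replicate 1 most, where 3 counts are 328 CPM.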

Other observations

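All tests in this part were chosen after the results were seen. Beyond the lists, neighbouring miRNA genes of the X chromosome (miR-450a, miR-450b, miR-542, miR-351, miR-503 and miR-322, neighbours in assembly GRCr8) were looked at because miR-450a-5p led the comparison. Of 5 tested forms 4 were higher in Exo-AT by edgeR's test: miR-450a-5p (at least 76.5-fold), miR-450b-5p (log2 fold change 4.91, SE 0.68), miR-542-3p (3.76, SE 0.87) and miR-351-5p (3.01, SE 1.16). miR-322-5p was not called. miR-351-5p had 0 counts in Exo-AT replicate 1, and nearly all miR-450b-5p reads of Exo-AT also align to miR-450a, so these are not 4 separate measurements. With DESeq2 size factors 3 were called higher.

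In the authors' deposited table most folds are larger than those from tag counts. Of the 44 tested miRNAs, miR-450a-5p is an apparent exception (56.7 against at least 76.5). Without the 10 added to both means its deposited fold is 75.0. Its bound rests on 0 counts in Exo-ADSCs replicate 2, where the deposited value is 27. miR-379-5p, miR-9a-5p and miR-204-5p (deposited folds within the counting intervals of their ratios) and miR-203b-3p and miR-150-5p (known only as bounds) are undecided. Scaling to all aligned reads, predicted hairpins included, may account for the size: the totals implied by the factors of 3 columns, for values scaled to 1000000 reads, were 99.9%, 102% and 106% of all aligned reads (largest deviation 6.07%) but 735%, 135% and 176% of the named counts, and the named share was 5.53 times higher in Exo-AT replicate 2 than in Exo-ADSCs replicate 2. Whether it accounts for the whole rise is open, since 22 of the 44 were called higher with TMM but the authors chose them as raised on the same libraries. Counting of only the most abundant tag in an Exo-AT column does not account for the larger folds, because counting all tags would raise those values, by a median ratio of 2.

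The columns of that table differ in how they relate to the tag counts. Its first Exo-AT column equals the counts of all tags of Exo-AT replicate 2 times 5.44 in 36 of 45 miRNAs, within 2%, and so the replicate numbers of the columns and of the tag counts conflict; which of them is wrong was not settled. Its second Exo-AT column equals the most abundant tag of Exo-AT replicate 1 times 62.3 in 29 of 45. The second Exo-ADSCs column equals the counts of all tags of Exo-ADSCs replicate 2 times 1.40 in 25 of 41. It lists miR-450a-5p at 27 in that column, where the tag counts hold 0.

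In Exo-ADSCs replicate 2, 10.4% of the named counts compared began 3 nt before the usual start, against 0 in Exo-AT replicate 1 and 0.011% in Exo-AT replicate 2, and 72.2% of let-7a-5p and 53.2% of miR-486-5p counts did. Cleavage of the precursor 3 nt further out does not account for them, since 0.0200% of them matched the hairpin without a mismatch. Bases added to the 5′ end that the hairpins do not hold may explain them, since 99.98% carried a mismatch, and the first bases were GTA in 11 of 21 miRNAs (1457 counts of the leading tags) and GAC in 2 (7782 counts, mostly let-7a-5p). The let-7a-5p difference does not rest on them: without them its log2 fold change was -3.83 (adjusted p = 1.21e-26, edgeR). No biological explanation was tested, and tags with more than 1 difference are not in the tag counts.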
